A study of Mus musculus with 6 samples.

How the data were processed

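RNA of regulatory T cells from 2 mouse genotypes, Blimp1 +/gfp and Blimp1 gfp/gfp, was measured on Illumina BeadChips, with 3 arrays per genotype. Per the labels, the RNA was amplified and labelled with Cy3. Groups and replicate numbers were taken from the labels. The labels also give a BeadChip and a section for each array: 1 of 2 BeadChips held the 3 Blimp1 +/gfp arrays and the other the 3 Blimp1 gfp/gfp arrays, so no term for the BeadChip could be fitted.

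The deposited signal table holds a mean bead intensity for each of 46632 probes on each array, on a linear scale. It was neither background-subtracted nor normalized, as its values show: the lowest lay between 67.9 and 80.5, and the medians between 157.4 and 164.8. Per the file headers, the authors also deposited a detection p-value for each probe and array. Per the submitters' processing notes, BeadStudio and limma were used, and their versions and settings are not given in the sources used here. A further table holds the authors' deposited log2 values of the same arrays. Set against limma's neqc applied to the intensities and detection p-values, these log2 values differed by at most 0.0975 and by a median of 0.00293, and each column's rank correlation with its own intensities was 1. Column medians of the deposited log2 values were 5.234 to 5.236. The scale, centring and direction of that table are therefore known from this comparison, and it was used as an alternative only.

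The intensities were processed with neqc in limma 3.58.1 under R 4.3.3: normexp background correction with negative-control parameters inferred from the detection p-values, an offset of 16, quantile normalization and log2. Intensities near background are compressed by the offset, so differences of dim genes are understated. Genes were named from the platform annotation, in which 29976 probes had 1 symbol, 10 several and 16646 none. Of the first, 29921 were matched by Entrez ID to RefSeq genes of GRCm38.p6, and 0 symbols changed. A probe with no name here was not counted as a gene. Probes with a detection p under 0.05 on at least 3 of the 6 arrays were kept (15800, of which 12042 had 1 symbol), and each gene was represented by its probe with the highest mean over all 6 arrays, which left 8743 genes. Of these, 2498 had more than 1 kept probe.

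The genotypes were compared with limma (lmFit and eBayes) as Blimp1 gfp/gfp minus Blimp1 +/gfp, with Benjamini-Hochberg adjustment over the 8743 genes and a threshold of 0.05. Differences are given with the standard error of the fit, and group values as the mean and SD of 3 arrays. Where a gene was not detected on any array of a group, its fold is a bound: the brighter group's mean log2 value over the other group's mean of, per array, the higher of the gene's own value and the lowest normalized value among detected probes. The bound is for group means and does not take in the spread between arrays, so a confidence interval can begin below it. On simulated data for these 8743 genes, 45 of 100 genes changed by a log2 difference of 1 and 87 of 100 changed by 2 were recovered, all with the right sign, and 8 of the 140 calls were false.

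The 22 gene lists were fixed before the data were examined, and so were the genes to name: every Prdm1 probe, the 10 largest differences in each direction among changed genes without overlap between genotypes (symbols of unnamed clones passed over, which was 1 gene, Gm4951, among the lower), up to 4 changed members of each list or the 2 with the smallest p where none changed, and 12 genes by name whatever their p. The rule gave 71 genes, of which 69 were tested. Lists were tested with camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 22 lists, and 8 lists passed. With a correlation estimated for each list, 0 of the 22 passed. On simulated data with noise drawn independently for each gene, 1 of 100 unchanged lists had a camera p under 0.05. This does not check lists whose genes vary together. The estimated correlations of the 22 lists ran from -0.00695 (genes known as Blimp-1 targets) to 0.909 (cell cycle genes).

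Alternatives fixed before the data were examined were other background corrections, normalizations, filters on dim probes, probe summaries, variance models, array weights, a replicate block, the deposited log2 values, other thresholds, fry in place of camera, and the omission of each array. Added after seeing the data were a covariate made of the myeloid and antigen presentation markers, the autosomal genes only, a test of every kept probe, the omission of each array with the probe of Prdm1 kept, and a covariate made of the B cell markers for Blk and Pou2af1. The range printed for a list over the alternatives is of camera, and it leaves out fry and the estimated correlation. Probes without a single gene name were left out of the gene comparison. Figures were drawn with matplotlib.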

Results

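Gene expression was measured in regulatory T cells of mice with 1 or both copies of Blimp1 replaced by a gfp allele. Regulatory T cells are the CD4 T cells that restrain immune responses, and Blimp1, a transcriptional repressor encoded by the gene Prdm1, is known for its part in the final differentiation of plasma cells and effector T cells. The labels call the genotypes Blimp1 +/gfp and Blimp1 gfp/gfp, give bone marrow as the tissue and C57/B6 as the strain, and name 3 samples of each genotype. They name no sort or gate by which the cells were obtained. From general knowledge of this allele, a gfp cassette inserted into Prdm1 lets cells be seen by their fluorescence, and cells with 2 gfp copies lack functional Blimp-1. The design asks which transcripts differ between regulatory T cells without functional Blimp-1 and those that keep 1 working copy. Each sample was hybridised to 1 Illumina array of 46632 probes, on which 14694 to 16067 probes were detected (31.5% to 34.5%). The number of arrays, 3 per genotype, limits the precision of each comparison. Nothing in the labels says that the 3 samples of a genotype came from separate animals, so the p-values measure the spread between these samples, which may be technical.

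Prdm1 itself was higher in Blimp1 gfp/gfp on the brighter of its 2 probes, ILMN_2744650. Its normalized log2 intensities were 5.76, 5.82 and 5.50 on the Blimp1 +/gfp arrays and 7.14, 7.75 and 7.54 on the Blimp1 gfp/gfp arrays. It was detected on 1 of 3 Blimp1 +/gfp arrays and on 3 of 3 Blimp1 gfp/gfp arrays. The log2 difference was 1.79 ± 0.20 (SE), past the threshold in limma with a Benjamini-Hochberg adjusted p of 0.00744. The call of Prdm1 ended with a mean over both probes (limma, Benjamini-Hochberg adjusted p = 0.102, range over the alternatives 0.00168 to 0.102). It also ended without Blimp1 gfp/gfp replicate 1 (0.0931), where ILMN_2597923 became the brighter probe, while ILMN_2744650 itself, kept as an alternative chosen after seeing the data, differed there by 1.95 ± 0.18 (SE; limma, Benjamini-Hochberg adjusted p = 0.0144). The second probe, ILMN_2597923, differed by 1.09 ± 0.62 (SE) and was detected on 2 arrays of each genotype. Where the probes lie relative to the gfp cassette is not given in the sources used here, so Prdm1 checks nothing about the labels.

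The samples with 2 gfp copies had less transcript of Il10, a suppressive cytokine of effector regulatory T cells, and more of Ccr6, the receptor for the chemokine CCL20. Il10 fell by 4.27 ± 0.22 (SE) on the log2 scale, from 10.37 ± 0.37 to 6.10 ± 0.19 (SD, n = 3), a 19.3-fold difference in normalized intensity (limma, Benjamini-Hochberg adjusted p = 0.000816). Ccr6 rose by 3.55 ± 0.34 (SE), from 7.78 ± 0.28 to 11.33 ± 0.66 (SD, n = 3), with a limma, Benjamini-Hochberg adjusted p of 0.00585. In all, 360 of 8743 genes tested were past the threshold (limma, Benjamini-Hochberg adjusted p under 0.05), 212 of them higher and 148 lower in Blimp1 gfp/gfp. Of these, 174 were at least 2-fold higher and 104 at least 2-fold lower. The 3 values of each genotype did not overlap for any of the 360 genes. Over all tested genes they did not overlap for 2255 (25.8%), where chance gives 10%. The count of changed genes was 71, 82 and 348 without Blimp1 +/gfp replicates 1, 2 and 3, and 183, 120 and 97 without Blimp1 gfp/gfp replicates 1, 2 and 3.

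Among the 10 largest gains, Npy, which encodes neuropeptide Y, was not detected on any Blimp1 +/gfp array and was at least 69.9-fold higher in Blimp1 gfp/gfp by the group means, with a wide spread there (11.90 ± 1.84 SD, n = 3; limma, Benjamini-Hochberg adjusted p = 0.0103). The 95% interval of its fold, without the bound, was 27.4 to 409. Sostdc1, a secreted antagonist of BMP and Wnt signals, rose by 5.17 ± 0.31 (SE), with a limma, Benjamini-Hochberg adjusted p of 0.00147. Vat1l, Vdr, the vitamin D receptor, and Lce1a1, a gene of the cornified skin layer, were also below detection on every Blimp1 +/gfp array, and were at least 10.1-fold, 9.43-fold and 10.3-fold higher. The rest were Blk, a Src-family kinase typical of B cells (log2 difference 3.78 ± 0.36 SE), Stom, which encodes stomatin (3.63 ± 0.32), Gna14, a G protein subunit (3.60 ± 0.40), Ccr6 and Tm4sf5 (3.55 ± 0.37). Npy and Lce1a1 were each past the threshold in 1 of the 3 omissions of an array that could be tested, with Benjamini-Hochberg adjusted p in limma over the alternatives of 0.00291 to 0.0598 and 0.00552 to 0.0733. With the myeloid and antigen presentation marker covariate the call of Lce1a1 ended and that of Npy stayed (limma, Benjamini-Hochberg adjusted p = 0.0624 and 0.0438). Blk and Gna14 were detected on 1 Blimp1 +/gfp array, so the size of their differences is uncertain. Beside Blk, the B cell marker Cd79a was detected on 1 Blimp1 +/gfp array and on all 3 Blimp1 gfp/gfp arrays. Lce1a1 belongs to a family of similar genes, so its probe may also bind others.

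Among the 10 largest losses, Mgmt, a DNA repair methyltransferase, fell by 4.36 ± 0.16 (SE), with a limma, Benjamini-Hochberg adjusted p of 0.000122. Mmp9, a matrix metalloproteinase, fell by 4.09 ± 0.28 (SE), and the adjusted p in limma was 0.00284 after Benjamini-Hochberg. Rasd2, a small GTPase, fell by 4.58 ± 0.70, Fpr2, a formyl peptide receptor of phagocytes, by 3.51 ± 0.64, and Cables1, a cyclin-dependent kinase partner, decreased by 3.38 ± 0.51. Rasd2 and Fpr2 were each detected on 1 Blimp1 gfp/gfp array, so the size of their differences and their place among the largest are uncertain. Havcr2, which encodes the inhibitory receptor TIM-3, fell by 2.93 ± 0.39, and Crem, a cAMP-responsive transcription factor, fell by 2.90 ± 0.37. Fpr2 was highest (10.25) in Blimp1 +/gfp replicate 3, the sample with the most Fcer1g RNA, a myeloid marker (12.91). Mmp9 was 10.24 in Blimp1 +/gfp replicate 1, where the neutrophil transcript S100a8 was not detected, and 6.18 in Blimp1 gfp/gfp replicate 1, where the macrophage transcript Lyz2 was 10.28. The calls of Rasd2, Fpr2, Cables1, Havcr2 and Crem each ended when single arrays were left out, and over the alternatives the Benjamini-Hochberg adjusted p in limma ranged from 0.000711 to 0.0862, 0.00547 to 0.119, 0.000675 to 0.0851, 0.000987 to 0.064 and 0.00174 to 0.0589. Rasd2 and Cables1 were past the threshold in 1 of 6 omissions, Fpr2 and Havcr2 in 2 and Crem in 4. Eif2s3y and Kdm5d, both on the Y chromosome, were detected on all 3 Blimp1 +/gfp arrays and on 0 Blimp1 gfp/gfp arrays, at least 29.1-fold and 5.80-fold lower.

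**Figure D1:**
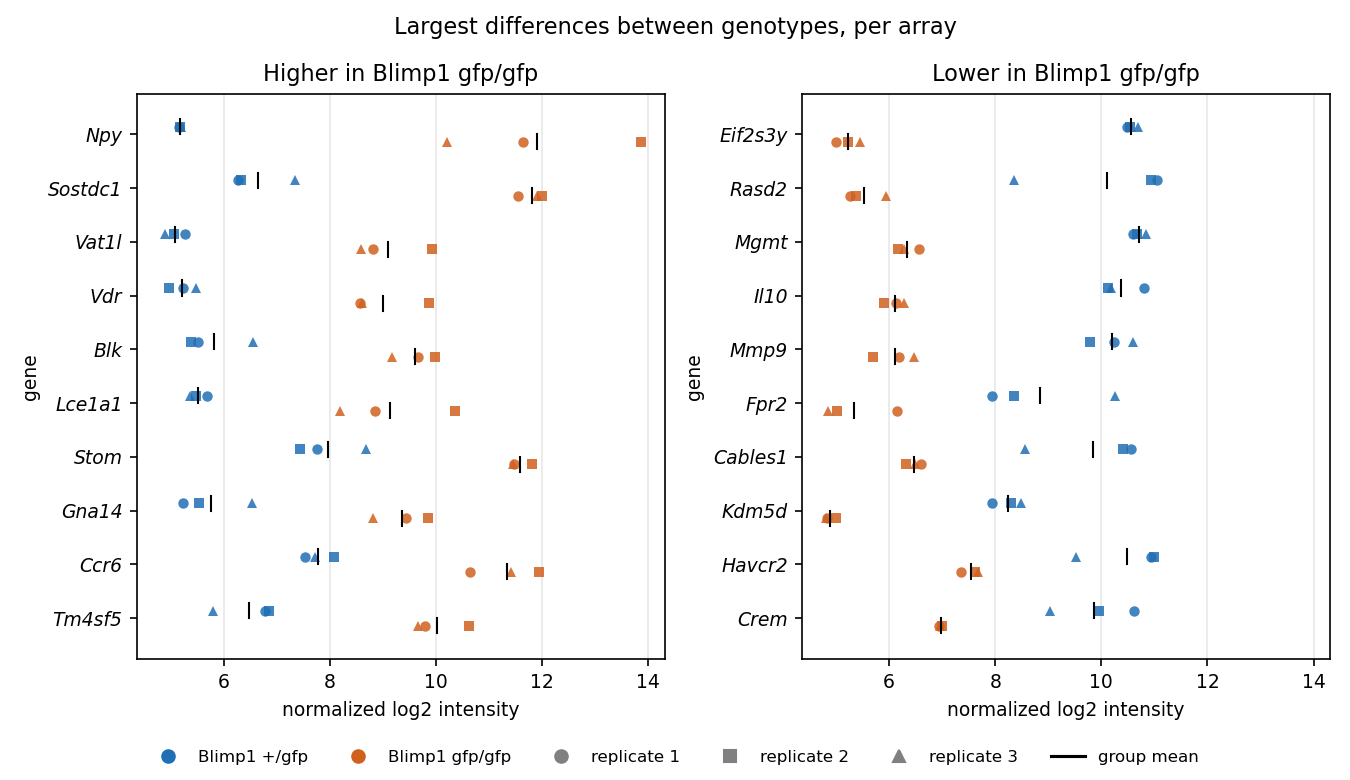
Normalized log2 intensity (x axis) of the 10 genes with the largest higher (left) and the 10 with the largest lower (right) log2 difference in Blimp1 gfp/gfp, for each of 6 arrays. Points are arrays, with a symbol per replicate, and vertical bars are group means of 3 arrays. Il10 lies between 10.14 and 10.80 in Blimp1 +/gfp and between 5.90 and 6.27 in Blimp1 gfp/gfp.

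The sex-linked transcripts differed within and between the genotypes. Xist, which is made from the inactive X chromosome of females, was 9.69 and 9.20 in Blimp1 +/gfp replicates 1 and 2, not detected in Blimp1 +/gfp replicate 3 (5.52), and 9.89, 11.37 and 11.02 in the 3 Blimp1 gfp/gfp samples. Eif2s3y, from the Y chromosome, was 10.49, 10.53 and 10.68 in Blimp1 +/gfp and was not detected in Blimp1 gfp/gfp. A further Y-linked gene, Uty, a histone demethylase relative chosen after its values were seen, was detected near background on all 6 arrays (6.57, 6.36 and 6.29 in Blimp1 +/gfp, 6.34, 6.08 and 5.93 in Blimp1 gfp/gfp), with a difference of -0.29 ± 0.16 (SE; limma, Benjamini-Hochberg adjusted p = 0.416). Both Xist and Eif2s3y were detected in Blimp1 +/gfp replicates 1 and 2, and the labels do not say whether a sample pooled animals. Eif2s3x, the partner of Eif2s3y on the X chromosome, rose by 0.84 ± 0.17 (SE), with a limma, Benjamini-Hochberg adjusted p of 0.0491. With autosomal genes only, an alternative chosen after seeing the data, 348 genes were past the threshold, 208 higher and 140 lower. Each genotype was also hybridised on a BeadChip of its own, so BeadChip and genotype cannot be told apart.

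Markers of other cell types varied between single samples. Fcer1g, an Fc receptor signalling chain, was 12.91 in Blimp1 +/gfp replicate 3 and between 7.80 and 9.73 in the other 5 samples. H2-Ab1, an MHC class II chain of antigen-presenting cells, was 14.47 in that sample and between 11.08 and 12.28 elsewhere. Lyz2, the lysozyme of macrophages, was 10.29, 10.55 and 10.94 in Blimp1 +/gfp, 10.28 in Blimp1 gfp/gfp replicate 1, and 7.35 and 7.16 in Blimp1 gfp/gfp replicates 2 and 3. S100a8, an abundant neutrophil transcript, was detected in Blimp1 +/gfp replicates 2 and 3 (9.49 and 9.97) and in no other sample. Of the 9 myeloid and granulocyte markers tested, 1 was higher, 0 were lower and the median log2 difference was -1.31 (camera, Benjamini-Hochberg adjusted p = 0.191). The 9 do not include S100a8 and S100a9, which differed by -2.80 and -2.04. Both were detected on 2 arrays, under the 3 needed. The member that rose was Cebpa, a transcription factor of myeloid differentiation, by 2.37 ± 0.28 (SE; limma, Benjamini-Hochberg adjusted p = 0.00872). Without Blimp1 gfp/gfp replicate 1 the camera adjusted p (Benjamini-Hochberg) of the myeloid list was 0.0082, and with median scaling it was 0.0251, in a range over the alternatives of 0.0082 to 0.683, and that of Cebpa in limma was 0.0549 without Blimp1 +/gfp replicate 1 (range 0.00174 to 0.0549).

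Of the 11 dendritic cell and antigen presentation markers, 1 was lower and 10 did not pass the test. The list's shift down had a camera adjusted p of 0.0174 (Benjamini-Hochberg), and an adjusted p = 0.649 with an estimated correlation. It was 0.444 without Blimp1 +/gfp replicate 3 and 0.0638 without Blimp1 gfp/gfp replicate 3, in a range over the alternatives of 0.00264 to 0.89. Irf8, a transcription factor of dendritic cells and some T cells, fell by 1.79 ± 0.33 (SE; limma, Benjamini-Hochberg adjusted p = 0.0348), and it was past the threshold in 1 of 6 omissions of an array and in 10 of 13 other settings (range over the alternatives 0.00825 to 0.125). Of 9 B cell and plasma cell markers, 0 passed in limma, with 1 higher and 0 lower at an unadjusted p under 0.05. Cd79a, part of the B cell receptor, was 5.94 ± 1.18 in Blimp1 +/gfp and 7.84 ± 0.62 in Blimp1 gfp/gfp (SD, n = 3; limma, Benjamini-Hochberg adjusted p = 0.146), and the list's median difference was 0.26 (camera, Benjamini-Hochberg adjusted p = 0.531, and 0.000546 with the myeloid and antigen presentation marker mean as a covariate, an alternative chosen after seeing the data, in a range of 0.000546 to 0.932). Cd79a passed under some alternatives (limma, Benjamini-Hochberg adjusted p 0.0176 to 0.327). Fcrla, a B cell protein related to Fc receptors, differed by 0.82 ± 0.42 (SE), and it passed with that covariate (limma, Benjamini-Hochberg adjusted p 0.0227 to 0.623 over the alternatives). Of 5 erythroid and megakaryocyte markers, 0 passed in limma, with 1 higher and 0 lower at an unadjusted p under 0.05 (camera, Benjamini-Hochberg adjusted p = 0.218). Hba-a1, a hemoglobin chain, lay between 5.78 and 13.40 within Blimp1 +/gfp, and Klf1, an erythroid transcription factor, was not detected on any Blimp1 +/gfp array and was at least 1.26-fold higher in Blimp1 gfp/gfp, without passing the test. Of 6 CD8 and NK cell markers, 0 passed in limma, and 0 at an unadjusted p under 0.05 (camera, Benjamini-Hochberg adjusted p = 0.422), where Eomes, a T-box factor, differed by 0.78 ± 0.41 (SE). The 13 general T cell markers held 0 changed genes in limma, with 0 higher and 3 lower at an unadjusted p under 0.05 (camera, Benjamini-Hochberg adjusted p = 0.218). Of these, Cd3e, a T cell receptor chain, differed by 0.02 ± 0.16 (SE), Cd2, an adhesion molecule, by -0.63 ± 0.20 and Trat1, an adaptor of the T cell receptor, by -1.13 ± 0.36.

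**Figure D2:**
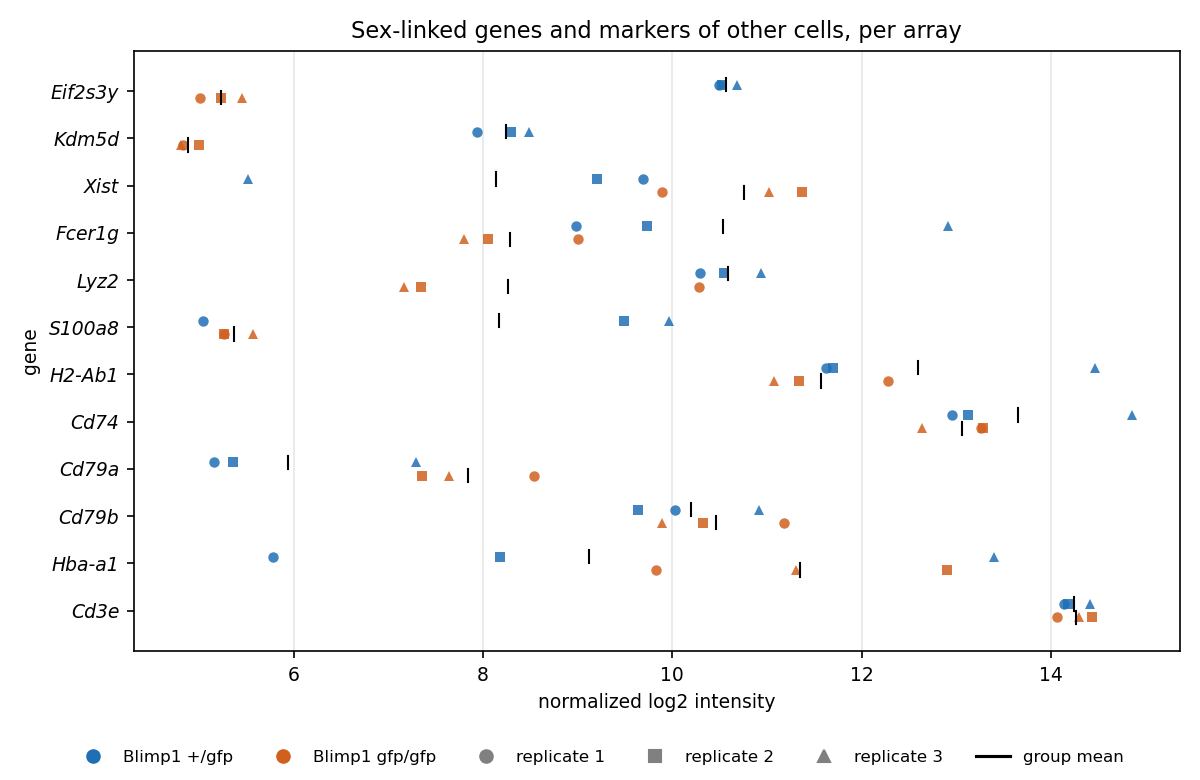
Normalized log2 intensity (x axis) of sex-linked genes, of markers of myeloid, antigen-presenting, B and red cells, and of Cd3e, for each of 6 arrays. Points are arrays, with a symbol per replicate, and vertical bars are group means of 3 arrays. Blimp1 +/gfp replicate 3 lies apart from the other arrays at Fcer1g (12.91) and at Xist (5.52).

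Of 18 regulatory T cell core genes tested, 1 was higher and 2 were lower, and adjusted over the list alone 2 were higher and 4 lower. Foxp3, the lineage-defining transcription factor, was 12.24 ± 0.40 in Blimp1 +/gfp and 11.96 ± 0.47 in Blimp1 gfp/gfp (SD, n = 3), a difference of -0.28 ± 0.30 (SE; limma, Benjamini-Hochberg adjusted p = 0.696). Ctla4, the inhibitory receptor of these cells, differed by -0.30 ± 0.19 (SE; limma, Benjamini-Hochberg adjusted p = 0.464). Tnfrsf18, which encodes GITR, fell by 1.11 ± 0.18 (SE) and Swap70, a signalling adaptor, by 1.13 ± 0.22, while Nt5e, which encodes the ectonucleotidase CD73, rose by 1.57 ± 0.32. The list shifted down in camera (Benjamini-Hochberg adjusted p = 0.0174), with an adjusted p = 0.463 with an estimated correlation, and it was 0.0868 without Blimp1 +/gfp replicate 3 and 0.122 without Blimp1 gfp/gfp replicate 1 (range over the alternatives 0.00746 to 0.122). The 3 probes of Swap70 differed in sign, from -1.17 to 0.04, and the calls of Tnfrsf18, Swap70 and Nt5e ended when single arrays were left out, and those of Swap70 and Nt5e also with the marker covariate (ranges of the Benjamini-Hochberg adjusted p in limma over the alternatives 0.00502 to 0.1, 0.00681 to 0.157 and 0.00651 to 0.151). That of Tnfrsf18 also ended with median scaling, that of Swap70 with a mean over probes and that of Nt5e with cyclic loess. Those of Swap70 and Nt5e ended with no filter on dim probes, and all 3 with the replicate block. Swap70 and Nt5e were past the threshold in 1 of 6 omissions of an array and Tnfrsf18 in 2.

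Effector genes of regulatory T cells moved in both directions. Of 17 tested, 2 were higher and 5 lower, and 4 and 5 adjusted over the list alone. Besides Il10 and Havcr2, Klrg1, a receptor of terminally differentiated effector cells, fell by 1.83 ± 0.26 (SE; limma, Benjamini-Hochberg adjusted p = 0.0145). Lag3, an inhibitory receptor that binds MHC class II, rose by 1.76 ± 0.20 (SE; limma, Benjamini-Hochberg adjusted p = 0.00815). Icos, a costimulatory receptor, differed by -0.22 ± 0.30 (SE; limma, Benjamini-Hochberg adjusted p = 0.779), and Irf4, a transcription factor of effector regulatory T cells, by 0.87 ± 0.25 (adjusted p = 0.114 in limma with Benjamini-Hochberg). Gzmb, which encodes granzyme B, was not detected on any of the 6 arrays. The list as a whole did not pass (camera, Benjamini-Hochberg adjusted p = 0.15), but it was 0.0269 without Blimp1 gfp/gfp replicate 2 and 0.00756 with the marker covariate (range over the alternatives 0.00756 to 0.72). Of 17 inhibitory and costimulatory receptors, 1 was higher and 5 lower, and 3 and 7 adjusted over the list alone. Tnfrsf9, which encodes 4-1BB, fell by 1.58 ± 0.26 (SE). This list shifted down in camera (Benjamini-Hochberg adjusted p = 0.0174), but had an adjusted p = 0.549 with an estimated correlation, and 0.0762 without Blimp1 gfp/gfp replicate 1 (range over the alternatives 0.00357 to 0.0762). The calls of Klrg1 and Tnfrsf9 ended when single arrays were left out, and that of Klrg1 also with the marker covariate (ranges of the Benjamini-Hochberg adjusted p in limma over the alternatives 0.00321 to 0.0743 and 0.00452 to 0.102). Klrg1 was past the threshold in 3 of 6 omissions and Tnfrsf9 in 2.

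Genes of follicular helper T cells, which guide B cells in germinal centres, shifted up in Blimp1 gfp/gfp. Of 12 tested, 4 were higher and 0 lower, and 5 and 1 adjusted over the list alone. Bcl6, the transcription factor that opposes Blimp-1, rose by 1.23 ± 0.15 (SE), with a limma, Benjamini-Hochberg adjusted p of 0.0109. Pou2af1, a transcriptional coactivator of B cells, rose by 2.46 ± 0.28 (limma, Benjamini-Hochberg adjusted p = 0.00744), Id3, an inhibitor of E proteins, by 2.04 ± 0.20 (0.00604), and Cxcr5, the receptor that leads cells to follicles, by 1.06 ± 0.21 (0.0398). The list shifted up in camera (Benjamini-Hochberg adjusted p = 0.0128), with an adjusted p = 0.463 with an estimated correlation, and 0.0868 without Blimp1 +/gfp replicate 3 and 0.0922 with the myeloid and antigen presentation marker covariate, an alternative chosen after seeing the data (range over the alternatives 0.000616 to 0.0922). Of the 9 B cell and plasma cell markers beside Pou2af1, 5 were positive and 4 negative, from Cd79a (1.91 ± 0.60 SE) and Ly6d (1.54 ± 0.91) to Cd79b (0.26 ± 0.43) and Mzb1 (-1.33 ± 0.69), and 0 passed in limma. With the mean of these markers as a covariate, an alternative chosen after seeing the data, Pou2af1 differed by 2.36 ± 0.26 and Blk by 3.64 ± 0.32 (SE; limma, Benjamini-Hochberg adjusted p = 0.0149 and 0.00918). That mean, centred, was -0.47, -0.68 and 0.63 in Blimp1 +/gfp and 1.13, -0.26 and -0.35 in Blimp1 gfp/gfp. Since it overlapped between the genotypes, the covariate cannot decide whether B cell RNA adds to these differences. The call of Cxcr5 ended whichever array was left out (range of the limma, Benjamini-Hochberg adjusted p over the alternatives 0.00862 to 0.159), and those of Bcl6 and Pou2af1 with some arrays left out (0.00167 to 0.0574 and 0.00153 to 0.0531). That of Cxcr5 also ended with a mean over probes, no filter on dim probes, the replicate block and the myeloid and antigen presentation marker covariate. Id3 stayed past the threshold whichever array was left out (highest 0.0428).

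Of 12 genes known as Blimp-1 targets, 3 rose, which were Bcl6, Cxcr5 and Id3, and 2 fell, which were Ifng, which encodes interferon gamma, by 2.72 ± 0.56 (SE), and Tbx21, which encodes the Th1 factor T-bet, by 1.87 ± 0.37. Adjusted over the list alone, 6 were higher and 2 lower, and the median difference was 0.93. The lists overlap, and 9 of these 12 genes are also in other lists. Bcl6, Cxcr5 and Id3 are also follicular helper genes, and Ifng and Tbx21 also T helper lineage genes, so these list shifts are not separate results. The list shifted up in camera (Benjamini-Hochberg adjusted p = 0.0282), with an adjusted p = 0.419 with an estimated correlation, and 0.113 without Blimp1 +/gfp replicate 1 and 0.0598 without Blimp1 +/gfp replicate 2. The same camera p was 0.0774 with median scaling, 0.0788 with genes detected on all 6 arrays and 0.0753 with a mean over probes, in a range over the alternatives of 0.00746 to 0.113.

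Genes of T helper lineages and of cytotoxic cells shifted down. Of 10 T helper lineage genes, 3 were lower, which were Ifng, Tbx21 and Ifngr1, a chain of the interferon gamma receptor that fell by 1.58 ± 0.22 (SE), and 1 was higher, which was Ccr6. Adjusted over the list alone, 1 was higher and 5 lower. The list shifted down in camera (Benjamini-Hochberg adjusted p = 0.0128), with an adjusted p = 0.603 with an estimated correlation, 0.0703 with no filter on dim probes and 0.0665 without Blimp1 gfp/gfp replicate 1 (range over the alternatives 0.000546 to 0.0703). Of 14 cytotoxic and NK receptor genes, 0 were higher and 3 lower, and 1 and 6 adjusted over the list alone. The chemokines Ccl4 and Ccl3, made by activated effector cells, fell by 2.44 ± 0.44 and 2.03 ± 0.38 (SE), and the third was Klrg1. This list shifted down in camera (Benjamini-Hochberg adjusted p = 0.000377), with an adjusted p = 0.419 with an estimated correlation. In fry its Benjamini-Hochberg adjusted p was 0.113. Of 15 cytokines, 1 was higher and 3 lower, and 2 and 5 adjusted over the list alone. Tnfsf11, which encodes RANKL, rose by 2.13 ± 0.39 (SE), and Ebi3, a subunit shared by IL-27 and IL-35, fell by 1.29 ± 0.15 along with Il10 and Ifng. The cytokines as a list did not pass (camera, Benjamini-Hochberg adjusted p = 0.0742), but it did without Blimp1 +/gfp replicate 3 (0.00473), without Blimp1 gfp/gfp replicate 3 (0.0367), with median scaling (0.0251), with detection on all 6 arrays (0.0242) and with the marker covariate (0.00756; range over the alternatives 0.00473 to 0.168). The calls of Ifng, Tbx21, Ifngr1, Ccl4, Ccl3, Tnfsf11 and Ebi3 ended when single arrays were left out, and those of Tbx21, Ccl4, Ccl3 and Tnfsf11 also with the myeloid and antigen presentation marker covariate (ranges of the Benjamini-Hochberg adjusted p in limma over the alternatives 0.0134 to 0.156, 0.0207 to 0.148, 0.00269 to 0.0733, 0.0132 to 0.122, 0.00491 to 0.132, 0.00588 to 0.122 and 0.00182 to 0.0511). Ifng, Tbx21 and Tnfsf11 were past the threshold in 1 of 6 omissions, Ccl3 in 2, Ifngr1 and Ccl4 in 3 and Ebi3 in 4. With the replicate block the calls of all but Ebi3 ended. With no filter on dim probes those of Ifng, Tbx21, Ccl3 and Tnfsf11 ended. That of Ifng also ended with a trended, robust variance model and that of Tbx21 with array weights.

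Interferon-stimulated genes shifted down as a group. All 18 members tested had a negative log2 difference, with a median of -0.58, 3 of them were past the threshold, and 9 were lower adjusted over the list alone. Oas1g, an antiviral RNA sensor, fell by 1.51 ± 0.21 (SE), Isg20, an exonuclease, by 1.20 ± 0.18 and Ifit2, an inhibitor of translation, by 0.91 ± 0.14. The list shifted down in camera (Benjamini-Hochberg adjusted p = 1.82e-09), with an adjusted p = 0.419 with an estimated correlation. The calls of Oas1g, Isg20 and Ifit2 ended when single arrays were left out, and those of Oas1g and Ifit2 also with the marker covariate (ranges of the Benjamini-Hochberg adjusted p in limma over the alternatives 0.00284 to 0.0661, 0.0065 to 0.0792 and 0.0062 to 0.0836), and Oas1g has near-identical relatives that its probe may also bind. That of Ifit2 also ended with median scaling, and those of Ifit2 and Isg20 with the replicate block. Ifit2 and Isg20 were past the threshold in 1 of 6 omissions of an array and Oas1g in 3.

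Receptors that steer migration changed in both directions. Of 19 chemokine receptors and homing receptors, 4 were higher and 1 lower, and 6 and 4 adjusted over the list alone. Besides Ccr6 and Cxcr5, Cxcr4, the receptor that holds cells in bone marrow, rose by 1.36 ± 0.15 (SE; limma, Benjamini-Hochberg adjusted p = 0.00744). Ccr4, a receptor for skin homing, was not detected on any Blimp1 +/gfp array and was at least 1.80-fold higher. Ccr2, a receptor for inflamed tissue, fell by 1.94 ± 0.33 (SE; limma, Benjamini-Hochberg adjusted p = 0.0256). The list did not pass (camera, Benjamini-Hochberg adjusted p = 0.817), and its median (-0.00) and mean (0.08) lay on either side of 0. The calls of Ccr4 and Ccr2 ended when single arrays were left out, and that of Ccr4 also with the marker covariate (ranges of the Benjamini-Hochberg adjusted p in limma over the alternatives 0.0289 to 0.116 and 0.00933 to 0.0938). Ccr4 was past the threshold in 0 of the 3 omissions that could be tested, and Ccr2 in 1 of 6. Both calls also ended with the replicate block, and that of Ccr4 with an offset of 50 and without background correction.

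Of 13 naive and central T cell genes, 2 rose and 1 fell, and 4 and 3 were past the threshold adjusted over the list alone. Klf2, a factor that maintains quiescence and recirculation, rose by 1.44 ± 0.15 (SE; limma, Benjamini-Hochberg adjusted p = 0.00716), as did Id3. Ly6c1, a surface protein with a near-identical relative, fell by 2.82 ± 0.58 (SE; limma, Benjamini-Hochberg adjusted p = 0.0485), and it was past the threshold in 2 of 6 omissions of an array and in 8 of 13 other settings (range over the alternatives 0.0191 to 0.158). Ccr7, the lymph node homing receptor, differed by 0.80 ± 0.25 (SE; limma, Benjamini-Hochberg adjusted p = 0.15). The list did not pass (camera, Benjamini-Hochberg adjusted p = 0.77), and its median (-0.06) and mean (-0.02) were negative where the test's direction was up.

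Housekeeping and stress groups held few changed genes. Of 25 cell cycle genes, 0 passed in limma, with 1 higher and 1 lower at an unadjusted p under 0.05 (camera, Benjamini-Hochberg adjusted p = 0.817), and Mcm6, of the replicative helicase, differed by 0.67 ± 0.19 (SE). Cks1b, a cyclin kinase subunit, was not detected on any Blimp1 gfp/gfp array and was at least 1.22-fold lower there, without passing the test. The direction of the cell cycle list's test was down while the median (0.07) and mean (0.06) were positive. Of 18 apoptosis and survival genes, 0 passed in limma, with 1 higher and 3 lower at an unadjusted p under 0.05 (camera, Benjamini-Hochberg adjusted p = 0.146), and with 1 higher and 1 lower adjusted over the list alone. Bcl2 and Bcl2l1, both survival genes, differed by 1.23 ± 0.26 and -1.41 ± 0.34 (SE; limma, Benjamini-Hochberg adjusted p = 0.0536 and 0.0748), and both passed under some alternatives (0.00714 to 0.18 and 0.0325 to 0.198). The list passed in camera with the marker covariate (Benjamini-Hochberg adjusted p = 0.0372, range over the alternatives 0.0372 to 0.552). Of 18 immediate-early and activation genes, 1 rose, which was Egr2, a zinc finger factor of T cell tolerance, by 1.13 ± 0.18 (SE), and the list did not pass (camera, Benjamini-Hochberg adjusted p = 0.983). Its median (-0.08) and the test's direction were negative and its mean (0.12) positive. Of 13 glycolysis genes, 1 fell, which was Slc2a3, a glucose transporter, by 1.02 ± 0.14 (camera, Benjamini-Hochberg adjusted p = 0.246, 0.0227 without Blimp1 +/gfp replicate 3 and 0.0219 with the marker covariate, range over the alternatives 0.0219 to 0.659). Of 13 heat shock and stress genes, 0 passed in limma, with 2 higher and 3 lower at an unadjusted p under 0.05 (camera, Benjamini-Hochberg adjusted p = 0.282), where Xbp1, a factor of the unfolded protein response, differed by -0.66 ± 0.16 (SE) and Ddit4, an inhibitor of mTOR, by 0.83 ± 0.28. The calls of Egr2 and Slc2a3 ended when single arrays were left out, that of Egr2 also with the marker covariate and that of Slc2a3 also with median scaling (ranges of the Benjamini-Hochberg adjusted p in limma over the alternatives 0.00386 to 0.0965 and 0.00248 to 0.0733). Each was past the threshold in 2 of 6 omissions, and both calls ended with the replicate block.

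**Figure D3:**
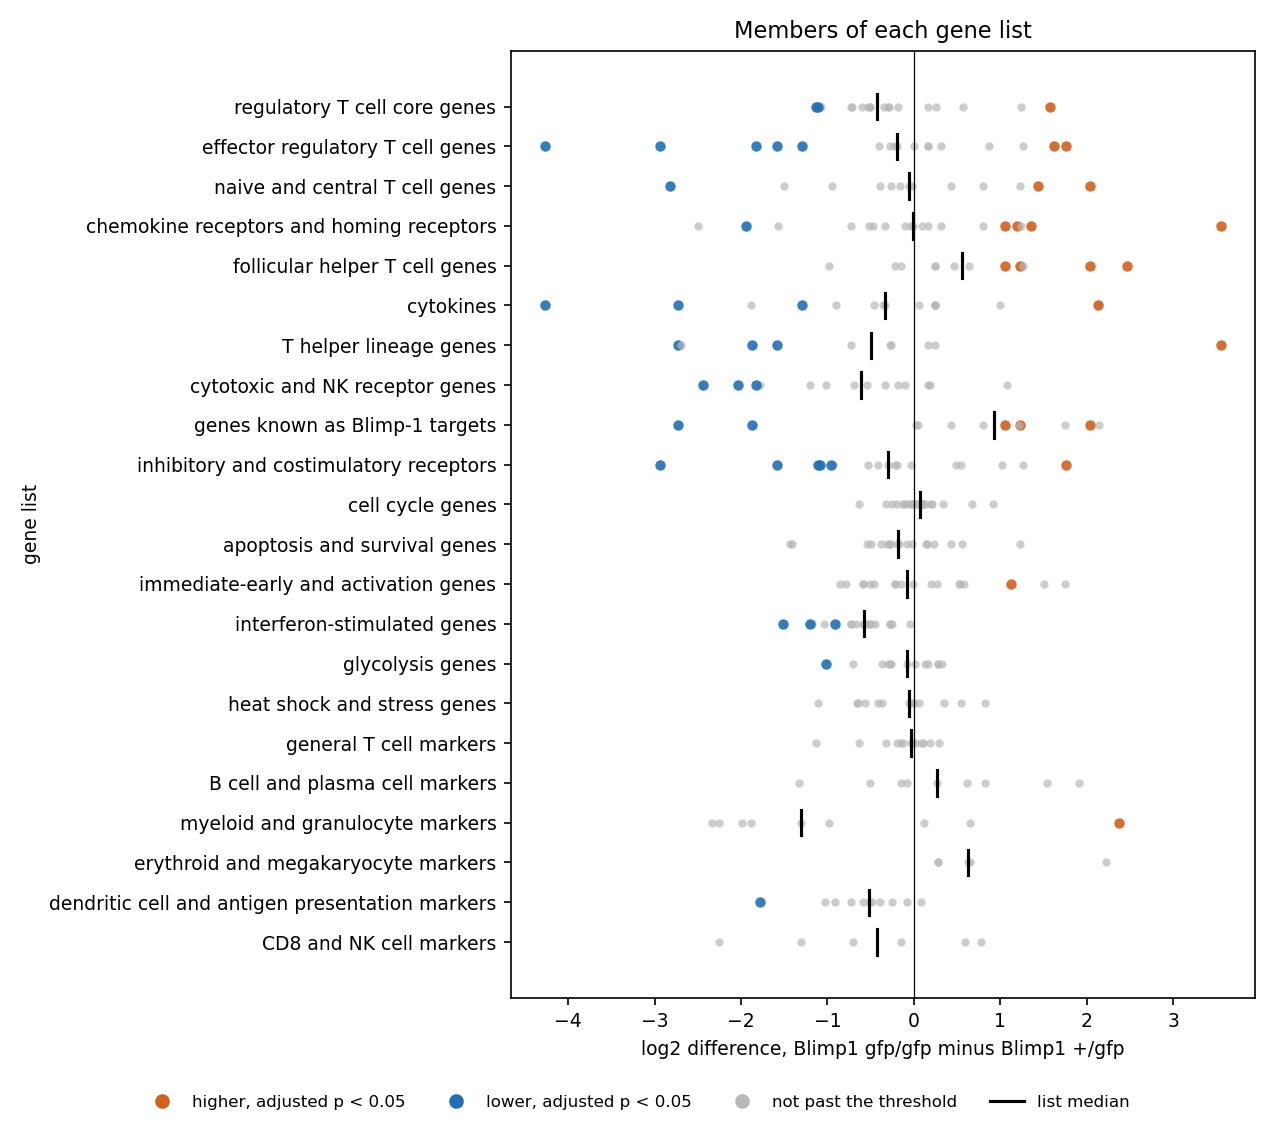
Log2 difference between Blimp1 gfp/gfp and Blimp1 +/gfp (x axis) of each tested member of the 22 gene lists (y axis). Points are genes, coloured where past the threshold in limma (adjusted p under 0.05), and vertical bars are list medians. All 18 interferon-stimulated genes lie below 0, and the 25 cell cycle genes lie on both sides of it.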

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

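The tests with either marker covariate, with autosomal genes only, with probes in place of genes and with the probe of Prdm1 kept were chosen only after the results were seen. Against 360 changed genes (212 higher, 148 lower in limma), array weights gave 827 (492 and 335), the replicate block 171 (108 and 63), the marker covariate 155 (95 and 60), an adjusted p under 0.01 71 (51 and 20) and complete separation 2255 (1346 and 909), where chance separates 10%. Median scaling gave 294 higher and 120 lower genes and cyclic loess 194 and 165, so the balance of directions depends on the scaling. Unnamed probes included, 514 probes changed, 289 higher and 225 lower. With 1 array left out, 71 to 348 genes changed, 54 to 216 higher and 15 to 132 lower, and genes detected on the 3 arrays of 1 group alone could not be tested without an array of that group. Whether replicate numbers pair the samples stays open. Deviations of like-numbered samples correlated across genes at 0.189, -0.0759 and 0.00102, and those of unlike-numbered samples at -0.148 to 0.165. With 3 samples per genotype these values cannot settle it. The log2 difference of Prdm1 was 1.44 with a mean of probes and 1.65 to 1.85 with an array left out, where the omission of Blimp1 gfp/gfp replicate 1 switched to ILMN_2597923 (1.78, limma, Benjamini-Hochberg adjusted p = 0.0931). With ILMN_2744650 kept, it was 1.65 to 1.95 with an array left out, and past the threshold in each of the 6 omissions.

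Of 22 lists, 8 passed in camera, 0 with an estimated correlation and 2 in fry, each a test of a shift up or down. The 2 were the interferon-stimulated genes and the genes known as Blimp-1 targets (fry, Benjamini-Hochberg adjusted p = 0.0384 for each). The other lists that passed in camera had adjusted p of 0.113 to 0.377 in fry (Benjamini-Hochberg). Fry's mixed test, against no change, also counts members that move in opposite directions. Its Benjamini-Hochberg adjusted p was 2.99e-05 for effector genes, 6.61e-05 for cytokines, 0.000116 for chemokine and homing receptors and 0.000118 for naive and central genes. It was 0.000255 for immediate-early genes and 0.00115 for glycolysis genes, but 0.552 for cell cycle genes and 0.416 for B cell markers. Lists that did not pass and whose direction turned had these Benjamini-Hochberg adjusted p, in camera unless fry is named, which tests a list against no change and not against other genes: chemokine and homing receptors 0.996 with median scaling and 0.683 with the covariate, cell cycle genes 0.981 with detection p under 0.01, 0.943 with detection on all 6 arrays and 0.941 in fry. For immediate-early genes these were 0.982 with an offset of 50, 0.97 without background correction, 0.963 with loess, 0.897 with no filter, 0.864 with the replicate block and 0.687 in fry. With an array left out, the ranges over all 6 omissions, whether or not the direction turned, were 0.402 to 0.925 for naive and central genes, 0.402 to 0.827 for chemokine and homing receptors, 0.0546 to 0.995 for cell cycle genes, 0.245 to 0.933 for immediate-early genes and 0.0868 to 0.911 for B cell markers. The cause was not tested.

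Of 50 named genes past the threshold, 17 stayed past it with each array left out in turn, and 13 of those could be tested in all 6 omissions. Under every other setting 26 stayed past it. Named genes not past the threshold passed it in 23 of 348 values, for Bcl2, Bcl2l1, Cd79a, Cks1b, Ddit4, Fcrla, Mcm6 or Xbp1, and lists that had not passed did so in 13 of 287 values. Median scaling moved the median of all genes to 0.16, from 0.03. The offset compresses signals near background, which limits the size of differences among dim genes.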

Other observations

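All tests in this part were chosen only after the result was seen, and so were the gene families and genes named here. Interferon-inducible GTPases, which act against pathogens inside cells, were picked because members had been seen to be lower in Blimp1 gfp/gfp, so no test of the family is given: 6 of 8 tested fell and 0 rose in limma, with a median log2 difference of -1.37. Gbp7 fell by 2.02 and Igtp by 1.45 on the log2 scale (limma, Benjamini-Hochberg adjusted p = 0.0269 and 0.00744). The median was negative under each scaling tried, and the probes of this family could not be checked for binding to near-identical relatives. Of 9 genes of the IL-12 and IL-18 pathway, which drives interferon gamma production and was picked in the same way, 3 fell and 0 rose in limma. Il12rb1, a receptor chain for IL-12, fell by 1.18 and Il18rap, a receptor chain for IL-18, by 1.54 (limma, Benjamini-Hochberg adjusted p = 0.0209 and 0.027). Of the other families looked at, dual-specificity phosphatases had 3 higher and 1 lower of 14, chemokine ligands 1 and 2 of 14, matrix metalloproteinases and their inhibitors 2 and 2 of 11, integrins 1 and 0 of 15, Schlafens 0 and 1 of 3 and the GIMAP family 0 and 1 of 6.

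Both subunits of soluble guanylate cyclase, the nitric oxide receptor, rose: Gucy1a1 by 2.82 ± 0.22 and Gucy1b1 by 1.30 ± 0.23 (SE; limma, Benjamini-Hochberg adjusted p = 0.00404 and 0.0321). Pde5a, which breaks down cyclic GMP, rose by 2.05 ± 0.27 (limma, Benjamini-Hochberg adjusted p = 0.0121). Lif, a cytokine of the IL-6 family, rose by 3.26 ± 0.31 (limma, Benjamini-Hochberg adjusted p = 0.00576). Of the 20 tested genes nearest to Prdm1, 2 passed the threshold (10%, against 4.12% of all tested genes), and these were Lilr4b and Lilrb4a, which fell by 1.37 and 0.96. These 2 genes lie next to each other among the tested genes, and whether their probes bind both was not checked. They may not be separate changes, so the 10% shows no excess near Prdm1.

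The count of 360 changed genes was weighed against the sex-linked differences and the layout of the arrays. Of the 360 genes, 348 were autosomal, so genes on the sex chromosomes do not make up the whole count. Autosomal genes were also 8479 of the 8743 genes tested, so this count cannot decide whether a sex difference is the cause. A sex difference acting on autosomal genes stays open: 39.4% of the changed autosomal genes lay, in Blimp1 +/gfp replicates 1 and 2, from replicate 3 towards Blimp1 gfp/gfp, against 53.9% of the others, but this rests on 1 array. BeadChip and genotype cannot be told apart, since 0 BeadChips held both. The 10 splits of the 6 arrays are too few for a share under 0.05: 1 split, the real one, gave 360 genes and the highest other gave 0.

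RNA of myeloid or antigen-presenting cells in the Blimp1 +/gfp samples may add to the genes lower in Blimp1 gfp/gfp. With the mean of 20 such markers as a covariate, the median log2 difference of the 147 lower genes outside the marker lists was -1.32, against -1.28 without it, and -1.35 to -1.25 with an array left out. That the median did not shrink cannot decide whether this RNA is the whole cause. The 147 genes were picked as changed on the same arrays. The centred marker mean varied within Blimp1 +/gfp (-0.16, 0.12 and 1.11), so genes that follow it were less likely to be picked. Of the 147, 53 were still past the threshold, and of the 94 whose calls ended, 43 had a smaller difference and 51 a larger or equal difference with a larger SE. The median SE of the 147 went from 0.19 to 0.23, and single genes such as Fpr2 stay open.

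A lower response to interferon is a candidate explanation for the interferon-stimulated genes. It was tested on the antigen-processing genes of MHC class I, also induced by interferon, after the GTPases and Tap1 had been seen to be lower. Their median was -0.42 over 13 genes, 12 of them negative and 1 past the threshold (Tap1), and -0.36 over the 12 genes without Tap1, of which 0 passed in limma. The marker covariate was not applied to these 13 genes. Their lower median therefore cannot tell a lower response to interferon from RNA of antigen-presenting cells in the Blimp1 +/gfp samples. With the marker covariate, the median of the 17 list members outside the marker lists was -0.50, against -0.57 without it. It was -0.74 to -0.38 with the covariate and an array left out. This argues against RNA that follows that marker mean as the whole cause. Myeloid RNA that the mean does not follow was not tested. Fewer cells that make interferon gamma, exposure in different animals and the sex of the animals were not tested.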
